A study of Mus musculus with 4 samples.

How the data were processed

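RNA sequencing measured gene expression in mouse Th17 cells, the helper T cells that make interleukin 17. Naive CD4+ T cells were enriched from 2 mice lacking PRAK and from 2 wild-type (WT) mice and were cultured under Th17-polarising conditions for 72 h, and all cells were then taken for total RNA extraction, per the labels. PRAK is the p38-regulated/activated protein kinase encoded by Mapkapk5. There was 1 library per mouse, so the 2 libraries of a genotype (called WT 1, WT 2, KO 1 and KO 2 after the mouse numbers in the labels) are separate animals, and any difference of culture that went with the mouse is part of their spread.

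The deposited table gives each gene's RSEM expected count, its FPKM and its TPM in each of the 4 libraries. Expected counts are the authors' estimates of reads per gene, not normalised, and 69.4% of the count values were whole numbers. FPKM values were scaled by the authors to gene length and library size, and TPM values were scaled by the authors to the same sum in each library, per the file headers and the values. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 with the mouse build GRCm38.p6, with no role or order for the tools. The labels name a BGISEQ sequencing platform. The library kit, whether strand was kept, the read length, the read filters and the annotation release are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and RSEM divides reads between near-identical genes by a model, so values of families such as the H2-Q genes, the Bcl2a1 genes, the metallothioneins and the histones are uncertain.

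The table held 17921 genes, of which 17787 were matched by gene ID to the RefSeq annotation of GRCm38.p6, from which all coordinates were taken. For 23 genes the symbol had been turned into a date and was restored through the gene ID, and 2 symbols occurred more than once. Transcripts of the mitochondrial genome were among the lists chosen and none was found by the symbols used, so these were not analysed here.

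Expected counts were rounded to whole numbers. Genes were filtered with the filterByExpr function of edgeR (minimum count 10, minimum total 15), which left 12680 genes and removed 5241. Libraries were scaled with TMM factors. The comparison of PRAK KO with WT was fitted in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust dispersion estimation, with genotype as the single term, and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are described as changed. All adjusted p-values of single genes come from this test unless another is named. Standard errors of log2 fold changes were computed from the fold change and the F statistic. Levels are CPM with TMM scaling, given as mean ± SD over the 2 libraries of a genotype. The total counts per library lay between 19418012 and 20125124. With 2 libraries per genotype the residual degrees of freedom were 2, raised by a prior of 3.58 degrees of freedom shared across genes. The number of mice and the depth both limit the precision, and the 2 limits were not compared.

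Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, with adjustment over the 34 lists that had members to test. Beside it stand camera with the correlation estimated from the data, and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. Of the 34 lists, 12 passed with the preset correlation, 8 higher and 4 lower in KO. With the estimated correlation 0 passed, 2 had an unadjusted p under 0.05, and the lowest adjusted p was 0.23. With fry 2 lists passed, glycolysis and hypoxia response. Each list also has a count of its members past the threshold over all genes and a count adjusted over the list alone.

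The design, the tests, the lists, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule names Mapkapk5, then 25 fixed genes of the Th17, NRF2 and glycolysis systems whatever their result. It then names the 10 genes with the largest log2 fold change in each direction among those that passed, with no overlap between the genotypes, a mean of at least 5 CPM and a gene name. Up to 4 members of each list with the smallest p-values complete it. Of these genes 2 are not reported here. Members of lists named beyond this rule were chosen after their values were seen. In the rule for the largest changes, 522 genes qualified higher in KO and 866 lower, of which 27 and 28 were unnamed predicted genes or pseudogenes and were counted only.

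The steps were tested on simulated data over 12680 genes, with the libraries' own sizes and each gene's mean level. The spread was the trend fitted over all 4 libraries, the same for both genotypes, and genes were drawn independently of each other. For the comparison of KO with WT, edgeR recovered 48 of 100 genes changed by a log2 fold of 1 and 92 of 100 changed by a log2 fold of 2, with 4 unchanged genes among 144 calls. Camera with the preset correlation found a list of 25 genes shifted by a log2 fold of -1 and called 0 of the 29 unshifted lists, while camera with the estimated correlation missed the shifted list. As the simulated genes were independent, this cannot show how the preset correlation performs on lists whose genes move together. The estimated correlation was 0.969 for MYC and ribosome biogenesis genes, 0.506 for p53 target genes and -0.00944 for glycolysis. Camera with an estimated correlation also takes its p-values from the 2 residual degrees of freedom, which camera with the preset correlation does not. A list not called by it is therefore not shown to be unchanged, or to owe its preset call to correlation between genes. Alternatives tried were other scalings, other filters on low counts, the mouse number as a block, each library left out in turn, DESeq2 1.42.0, limma with trend on log2(CPM + 1), log2(FPKM + 1) and log2(FPKM + 0.1), dispersion without the robust option, and a 2-fold minimum. TPM values were not used in a test. In a fit without 1 library, the genotype left with 1 library was assumed to vary like the other genotype. The p-values and calls of such fits therefore show how far a result rests on a library, and are not tests of a change in themselves.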

Results

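Gene expression was measured by RNA sequencing in Th17 cells grown for 72 h from naive CD4+ T cells of 2 PRAK KO mice and 2 WT mice. Total expected counts were 20125124 in WT 1, 19853344 in WT 2, 20027775 in KO 1 and 19418012 in KO 2. The mean KO total was 0.987 times the mean WT total. Between 15155 and 15715 genes had a count above 0 in a library. The WT libraries were closer to each other (Pearson r = 0.992 across genes, on log2 CPM) than the KO libraries were (r = 0.974), and r between the genotypes lay between 0.935 and 0.940. These are correlations across genes, which are not independent replicates. The chi-square per gene was 7.37 between the WT libraries and 59.8 between the KO libraries, so no 2 libraries of a genotype agreed within sampling noise. The first principal component held 75.4% of the variance and separated the genotypes. The second held 18.7% and separated KO 1 from KO 2.

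Mapkapk5, the gene of PRAK (gene ID 17165, chromosome 5, 121525051 to 121545892, GRCm38.p6), was lower in both KO libraries but not absent from them. Its level was 35.6 CPM in WT 1, 38.4 in WT 2, 20.04 in KO 1 and 21.6 in KO 2, a mean of 37.0 ± 1.97 CPM in WT against 20.8 ± 1.08 in KO (SD, n = 2 each). The log2 fold change was -0.83 with a standard error of 0.13 (adjusted p = 0.0194, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The direction matched the labels in all 4 libraries. The labels do not say which part of the gene was deleted, and a count over the whole gene can include reads from parts that were left, so it does not show how much intact transcript remained. The adjusted p was 0.0918 without WT 1 and 0.169 without WT 2.

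The comparison of PRAK KO with WT cells asks, by the title of the series, whether PRAK acts on Th17 differentiation, on NRF2 and redox balance, and on glycolysis. In KO cells 17 of 28 glycolysis genes fell, as did 21 of 24 genes of the hypoxia response and 14 of 23 of sterol synthesis, while 13 of 23 p53 target genes and several chemokine genes rose. Of 34 gene lists 12 were called with a preset correlation between genes, and 0 with a correlation estimated from the data, a test with 2 residual degrees of freedom. Of 12680 genes tested, 1695 changed, 652 higher and 1043 lower in KO (edgeR quasi-likelihood test, adjusted p under 0.05). At least a 2-fold change was found for 370 of the higher and 645 of the lower genes, and at least a 4-fold change for 186 and 268. In 63.0% of the genes tested the values of the 2 genotypes did not overlap, where chance gives 33.33%. Scaling by library size alone gave 918 higher and 864 lower genes, or 51.5% higher in place of 38.5%, and moved the median log2 fold change of all genes from 0.02 to 0.12, so the balance of rises and falls rests on the scaling. The number of genes called was 718 without WT 1, 693 without WT 2, 4726 without KO 1 and 5999 without KO 2.

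Among genes with a mean of at least 5 CPM, Tgfb3 and the glutamate receptor subunit gene Grin1 were among the 10 largest falls, and the chemokine genes Xcl1, Ccl6 and Cxcl3 were among the 10 largest rises. Xcl1 rose from 0.754 ± 0.413 CPM in WT to 41.5 ± 10.7 in KO (log2 fold change 5.77, adjusted p = 0.00258). Timd2 rose from 0.259 ± 0.00355 to 12.5 ± 3.02 (5.56, adjusted p = 0.00234), and Ccl6 rose from 0.857 ± 0.341 to 22.3 ± 0.449 (4.69, adjusted p = 0.00225). The others of the 10 were Lad1 (7.69), Robo3 (5.31), Ak1 (5.12), Cxcl3 (5.02), Clec4n (4.78), Sulf2 (4.76) and Zfp750 (4.49). Grin1 fell from 20.2 ± 3.75 to 0.319 ± 0.0287 CPM (log2 fold change -5.96, adjusted p = 0.00179). The integrin gene Itga7 fell from 239 ± 0.194 to 6.36 ± 1.33 (-5.23, adjusted p = 0.00179), and the incretin receptor gene Gipr fell from 177 ± 40.4 to 6.01 ± 0.564 (-4.87, adjusted p = 0.00179). The other large falls were those of Myh7b (-5.74), Tgfb3 (-5.62), Selenbp1 (-5.53), Muc2 (-5.22), Dntt (-5.09), Pkp2 (-4.86) and the metallothionein gene Mt2 (-4.75). Calls of 4 of these 20 genes were lost without a WT library. Without WT 1 the adjusted p was 0.468 for Lad1, 0.533 for Robo3, 0.0828 for Ak1 and 0.56 for Mt2. Without WT 2 it was 0.546, 0.548, 0.107 and 0.658. The log2 fold change of some genes moved by more than 1.5 times in fold, as for Lad1 (8.34 without KO 1, 6.46 without KO 2) and Robo3 (4.63 without WT 1, 6.59 without WT 2, 6.11 without KO 1, 3.35 without KO 2). It also moved for Xcl1 (6.46 without WT 2), Cxcl3 (4.33 without WT 1, 6.34 without WT 2, 4.37 without KO 2) and Mt2 (-6.56 without KO 1, -3.98 without KO 2). Without KO 2 alone, such moves were also seen for Ak1 (4.25), Clec4n (4.04), Sulf2 (4.06), Zfp750 (3.60), Selenbp1 (-6.18), Muc2 (-6.00) and Dntt (-5.70).

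The Th17 programme did not move as a block: 3 of 26 tested members rose, 5 fell and 18 did not pass (6 and 10 adjusted over the list alone). Tgfb3, a TGF-beta gene expressed by Th17 cells, fell from 129 ± 9.08 to 2.61 ± 0.951 CPM (log2 fold change -5.62 ± 0.25 SE, adjusted p = 0.00179). Il23r, the receptor chain for interleukin 23, fell from 31.2 ± 0.0856 to 9.10 ± 5.07 CPM (-1.77 ± 0.38 SE, adjusted p = 0.0390). Stat3, the transcription factor downstream of interleukin 6, fell from 986 ± 50.7 to 524 ± 13.5 CPM (-0.91 ± 0.14 SE, adjusted p = 0.0169). The chemokine receptor gene Ccr6 rose from 22.7 ± 0.275 to 49.3 ± 5.56 CPM (1.12 ± 0.14 SE, adjusted p = 0.00963). The cytokine gene Csf2 rose from 4.61 ± 0.303 to 16.7 ± 1.49 CPM (1.86 ± 0.20 SE, adjusted p = 0.00693). Ccl20 (2.2) also rose, and Socs3 (-1.06) and Il6ra (-0.76) also fell. The list as a whole had a median log2 fold change of -0.27 (camera adjusted p = 0.137, and adjusted p = 0.767 with an estimated correlation). Its adjusted p was 0.0233 without WT 2 and 0.000113 without KO 1. Without WT 1 it held 3 higher and 2 lower genes, without WT 2 it held 3 and 1, without KO 1 it held 7 and 17, and without KO 2 it held 8 and 11. Calls were lost for Il23r without WT 1 (adjusted p = 0.0763) or WT 2 (0.0721) and for Stat3 without WT 1 (0.166) or WT 2 (0.117), and without KO 1 the change of Il23r was -2.50.

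The signature cytokines differed more between the 2 KO mice than between the genotypes. Il17a (chromosome 1, 20730905 to 20734496) stood at 474 CPM in WT 1, 418 in WT 2, 643 in KO 1 and 237 in KO 2, with a log2 fold change of -0.02 ± 0.44 SE (adjusted p = 0.981), and its sign turned with scaling by library size alone (0.08). Il17f averaged 2106 ± 168 CPM in WT and 1316 ± 959 in KO (-0.68, adjusted p = 0.410), and Il22 averaged 231 ± 19.2 and 121 ± 97.6 (-0.93, adjusted p = 0.310). None of these 3 genes passed the test, and their changes depended on which KO library was kept. Without KO 1 the log2 fold changes were -0.91 for Il17a, -1.73 for Il17f and -2.16 for Il22. Without KO 2 they were 0.52 for Il17a, -0.08 for Il17f and -0.29 for Il22.

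**Figure D1:**
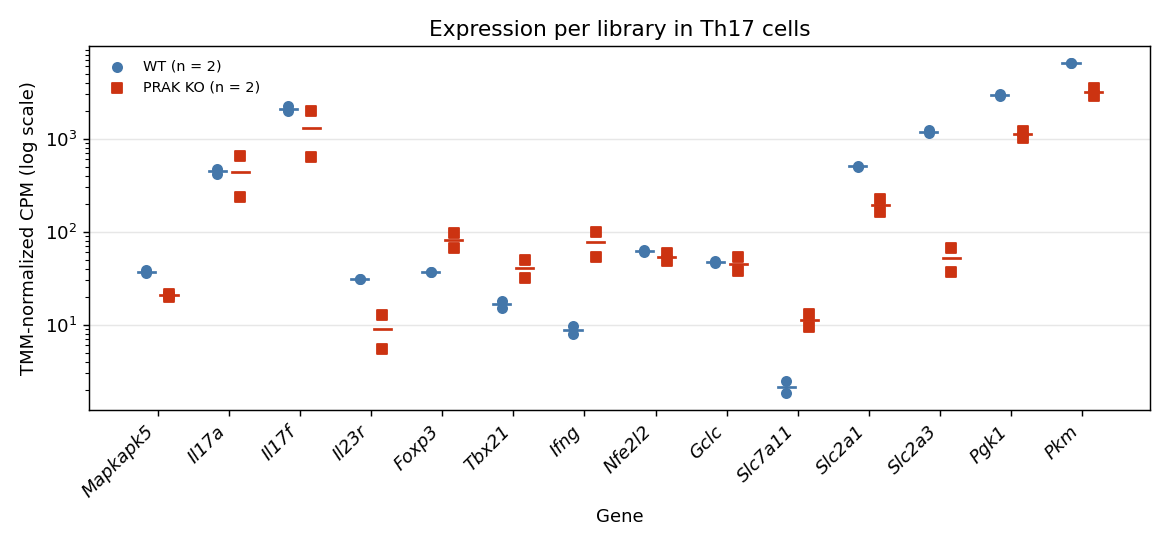
TMM-normalised CPM of 14 named genes (log axis), with circles for the 2 WT libraries, squares for the 2 PRAK KO libraries and a short line for each mean. Slc2a3 and Slc2a1 lie lower in both KO libraries than in both WT libraries, Ifng and Slc7a11 lie higher, and the KO values of Il17a lie on either side of the WT values.

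Other helper T cell genes also shifted, with Ifng and Foxp3 rising. In the Th1 programme 7 of 18 members rose, 2 fell and 9 did not pass (10 and 3 adjusted over the list alone), with a median log2 fold change of 0.94 (camera adjusted p = 7.91e-05, and adjusted p = 0.665 with an estimated correlation). Ifng, the interferon gamma gene, rose from 8.86 ± 1.22 to 77.0 ± 32.8 CPM (3.12 ± 0.33 SE, adjusted p = 0.00738). Ccl3 rose from 47.9 ± 6.84 to 288 ± 12.8 CPM (2.59, adjusted p = 0.00206). The lineage factor gene Tbx21 rose from 16.6 ± 1.91 to 40.4 ± 12.4 CPM (1.28, adjusted p = 0.0292, and 0.0584 without WT 1). Il12rb2, the receptor chain for interleukin 12, fell from 468 ± 63.1 to 163 ± 4.84 CPM (-1.52, adjusted p = 0.00567). The Th1 list held 4 higher genes and 1 lower without WT 1, 6 and 1 without WT 2, 12 and 3 without KO 1, and 8 and 4 without KO 2. Markers of myeloid cells, which also make Ccl3, rose in the same libraries (median log2 fold change 2.46). Of the 21 tested, 12 had a WT mean of at least 1 CPM. Ccl3 stood at 279 CPM in KO 1 and 297 in KO 2, and Ctss, the marker with the highest KO mean, at 56.1 and 98.0. Between KO 1 and KO 2 the markers moved both ways, as for Lyz2 (12.7 and 64.3), Itgax (9.34 and 12.6) and Flt3 (15.1 and 8.30). The share of Ccl3 that came from such cells was not measured, and these levels do not decide it. Markers of CD8 T and NK cells, which also make Ifng and Ccl3 and express Tbx21, had a median of 0.59 and were not called as a list, but Nkg7 among them rose (1.96, adjusted p = 0.0402) and Cd8a lay higher in both KO libraries.

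Treg markers split. Foxp3, the lineage factor of regulatory T cells, rose from 36.7 ± 0.210 to 82.1 ± 20.6 CPM (log2 fold change 1.16 ± 0.19 SE, adjusted p = 0.0215). By contrast, Ctla4 (-1.18, adjusted p = 0.0120) and Tnfrsf9 (-1.84, adjusted p = 0.0185) fell. In that list 4 of 18 rose and 2 fell (6 and 4 adjusted over the list alone), with a median of -0.05 and a test that pointed the other way (camera adjusted p = 0.872). In the Th2 programme 1 of 14 rose and 4 fell (3 and 5 over the list alone), among them Nfil3 (-1.83, adjusted p = 0.00280) and Ccr4 (-1.2, adjusted p = 0.0112). Its median was 0.49 (-0.12 without KO 2) although camera pointed lower (adjusted p = 0.569). Gata3, the Th2 lineage factor, averaged 19.7 ± 0.197 CPM in WT and 37.6 ± 33.1 in KO (0.93, adjusted p = 0.364), with 1.63 without KO 1 and -0.49 without KO 2. Of 17 naive T cell genes 1 rose and 2 fell (4 and 2 over the list alone), with a median of -0.15, a mean of 0.09 and a camera adjusted p of 0.872. These 3 calls, of Foxp1 (0.69), Il7r (-0.85) and Txk (-1.05), were lost without WT 1 (adjusted p = 0.178, 0.0530 and 0.0519) and without WT 2 (0.276, 0.0810 and 0.0640). Of 19 TGF-beta response genes 5 rose and 2 fell (8 and 4 over the list alone, median 0.19, camera adjusted p = 0.312). Among them Pmepa1 rose from 106 ± 7.30 to 280 ± 66.1 CPM (1.40, adjusted p = 0.0129). Ctla4 was not called without WT 2 (adjusted p = 0.0628). The counts of higher and lower genes were 3 and 2 without WT 1, 2 and 1 without WT 2, 9 and 7 without KO 1 and 7 and 8 without KO 2 for Treg markers. They were 0 and 2 without either WT library, 6 and 5 without KO 1 and 5 and 6 without KO 2 for the Th2 programme. For naive T cell genes they were 0 and 0 without either WT library, 7 and 3 without KO 1 and 6 and 9 without KO 2. In the TGF-beta response they were 3 and 1 without either WT library, 9 and 5 without KO 1 and 9 and 4 without KO 2.

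NRF2 target genes showed no shared direction. NRF2 is the transcription factor that drives antioxidant and detoxifying genes, and KEAP1 is the protein that holds it in check. Of 31 tested targets 1 rose, 3 fell and 27 did not pass (the same numbers adjusted over the list alone), with a median log2 fold change of 0.13 (camera adjusted p = 0.828). Slc7a11, the cystine transporter gene, rose from 2.15 ± 0.447 to 11.3 ± 2.60 CPM (2.39 ± 0.30 SE, adjusted p = 0.0106). Gstm1 fell from 16.5 ± 1.69 to 7.16 ± 0.282 CPM (-1.21, adjusted p = 0.0171), and the others that fell were Trim16 (-1.10, adjusted p = 0.0391) and Abcc1 (-0.55, adjusted p = 0.0332). Without WT 1 the adjusted p was 0.0607 for Gstm1, 0.0919 for Trim16 and 0.338 for Abcc1. Without WT 2 it was 0.154, 0.130 and 0.260. The list held 1 higher and 0 lower genes without either WT library, 5 and 9 without KO 1, and 6 and 6 without KO 2.

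The other fixed genes of this system did not pass the test. Nfe2l2, the gene of NRF2 itself, averaged 62.0 ± 1.62 CPM in WT and 53.7 ± 7.84 in KO (log2 fold change -0.21, adjusted p = 0.369), and Keap1 averaged 118 ± 1.73 and 88.6 ± 7.11 (-0.41, adjusted p = 0.0725). The values were 0.24 for Hmox1 (adjusted p = 0.343), -0.06 for Gclc (0.860), 0.19 for Gclm (0.533), 0.37 for Txnrd1 (0.254), 0.66 for Srxn1 (0.131) and 1.00 for Nqo1 (0.157), which lay at 1.14 ± 0.424 CPM in WT. The sign of Gclc turned with scaling by library size alone (0.04). Without KO 1 the log2 fold change was -0.37 for Nfe2l2, -0.50 for Keap1, 0.38 for Hmox1 and -0.33 for Gclc. Without KO 2 it was -0.34 for Keap1, 0.58 for Txnrd1 and 0.86 for Srxn1. Of 12 NRF2 regulators 0 rose and 0 fell (edgeR; 4 lower without KO 1, and 3 higher and 3 lower without KO 2), with a median of -0.18 and a camera adjusted p of 0.761.

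Among 34 antioxidant enzymes 2 rose, 1 fell and 31 did not pass (also 2 and 1 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 0.322). Sesn2, which is also a p53 and ATF4 target, rose from 28.8 ± 0.776 to 100.4 ± 21.6 CPM (1.80, adjusted p = 0.00604). Txn2, the mitochondrial thioredoxin gene, rose by 0.58 (adjusted p = 0.0328), and Prdx4, the peroxiredoxin of the endoplasmic reticulum, fell by 0.74 (adjusted p = 0.0235). Without WT 1 the adjusted p was 0.325 for Txn2 and 0.116 for Prdx4, and without WT 2 it was 0.301 and 0.177. The list held 1 higher and 0 lower genes without either WT library, 13 and 6 without KO 1, and 8 and 7 without KO 2. Of 9 genes that make reactive oxygen or regulate redox balance 2 rose and 1 fell (3 and 2 over the list alone, median 0.27, camera adjusted p = 0.569). These counts were 1 and 1 without WT 1, 2 and 0 without WT 2, 3 and 2 without KO 1 and 2 and 3 without KO 2. Cybb, a subunit of the phagocyte NADPH oxidase, rose from 5.23 ± 3.33 to 30.6 ± 3.49 CPM (2.55, adjusted p = 0.0232). That call was lost without KO 1 (adjusted p = 0.145) or KO 2 (0.188), its change was 3.40 without WT 2, and myeloid markers rose beside it (median 2.46). Of the other subunits of that oxidase, Cyba rose (0.57, adjusted p = 0.0278, 0.285 without WT 1 and 0.367 without WT 2). By contrast, Ncf1 fell from 195 ± 29.8 to 99.0 ± 19.2 CPM (-0.98, adjusted p = 0.0296, and 0.0959 without WT 2).

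Glycolysis genes were lower in KO cells. Of 28 glycolysis genes 17 fell, 1 rose and 10 did not pass (19 and 1 adjusted over the list alone), with a median log2 fold change of -1.01. The glucose transporter gene Slc2a3 fell from 1180 ± 62.8 to 51.6 ± 21.4 CPM (-4.52 ± 0.33 SE, adjusted p = 0.00321). Slc2a1, which encodes GLUT1, fell from 503 ± 13.7 to 193 ± 42.5 CPM (-1.38 ± 0.18 SE, adjusted p = 0.0123). Among enzymes, Hk1 fell from 845 ± 34.8 to 369 ± 8.39 CPM (-1.2, adjusted p = 0.00833) and Pgk1 from 2955 ± 69.3 to 1114 ± 149 CPM (-1.41, adjusted p = 0.0102). Pfkp fell from 932 ± 37.2 to 450.0 ± 11.1 CPM (-1.05, adjusted p = 0.0113) and Pkm from 6500 ± 26.2 to 3203 ± 446 CPM (-1.02, adjusted p = 0.0280). The lactate exporter gene Slc16a3 fell from 557 ± 43.2 to 194 ± 3.85 CPM (-1.52, adjusted p = 0.00459). Hk2 (-0.71, adjusted p = 0.0861), Ldha (-0.68, adjusted p = 0.0831) and Hif1a, the gene of the hypoxia factor HIF-1 alpha (-0.48, adjusted p = 0.0921), did not pass. The list was lower with camera (adjusted p = 4.85e-13) and with fry (adjusted p = 0.00359), but not with camera and an estimated correlation (adjusted p = 0.230). The estimated correlation, -0.00944, lay below the preset 0.01, so correlation between these genes does not account for the lost call. That test has 2 residual degrees of freedom. Without WT 1 or without WT 2 the number of lower glycolysis genes was 6 and that of higher ones 0, and the medians were -1.01 and -0.997. In these fits Pfkp (adjusted p = 0.0839 and 0.0579) and Pkm (0.225 and 0.253) were not called. Without KO 1 the log2 fold changes were -1.04 for Hk2, -0.90 for Ldha and -0.42 for Hif1a, and without KO 2 they were -0.45, -0.50 and -0.55.

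Genes of the hypoxia response were also lower. Of 24 genes 21 fell, 0 rose and 3 did not pass (24 and 0 adjusted over the list alone), and all 24 lay lower in both KO libraries than in both WT libraries. The median log2 fold change was -1.55, a WT level 2.93 times the KO level (camera adjusted p = 8.66e-42, fry adjusted p = 0.0154, and adjusted p = 0.230 with an estimated correlation). Ndrg1 fell from 881 ± 97.8 to 84.7 ± 23.9 CPM (-3.38 ± 0.25 SE, adjusted p = 0.00319). The oxidase gene Ero1l fell from 1304 ± 138 to 204 ± 22.1 CPM (-2.68 ± 0.17 SE, adjusted p = 0.00225) and the mitophagy gene Bnip3 from 374 ± 22.5 to 61.1 ± 2.40 CPM (-2.61 ± 0.13 SE, adjusted p = 0.00179). P4ha2, a prolyl hydroxylase of collagen, fell from 40.7 ± 5.10 to 4.59 ± 0.537 CPM (-3.15 ± 0.19 SE, adjusted p = 0.00209). Between 20 and 24 of the genes fell when any 1 library was left out.

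Genes of the mitochondrial and pentose phosphate pathways were not called as lists. Of 27 genes of the TCA cycle 2 fell and 0 rose (the same over the list alone, median -0.04, camera adjusted p = 0.685). Pcx, the pyruvate carboxylase gene, fell from 107 ± 1.06 to 14.4 ± 7.08 CPM (log2 fold change -2.89, adjusted p = 0.00884, and -3.51 without KO 1). Idh1 fell by 0.98 (adjusted p = 0.0250, 0.174 without WT 1 and 0.236 without WT 2). Of 76 nuclear genes of the respiratory chain 1 rose and 1 fell (0 over the list alone, median 0.02, camera adjusted p = 0.677). They were Atp5g1 (0.68, adjusted p = 0.0353, 0.206 without WT 1 and 0.234 without WT 2) and Ndufv3 (-1.08, adjusted p = 0.0204). Of 12 pentose phosphate genes 1 rose (0 over the list alone), Prps1 (0.52, adjusted p = 0.0497, 0.328 without WT 1 and 0.464 without WT 2), with a median of -0.11 and a camera test that pointed higher (adjusted p = 0.922). Without KO 1 and without KO 2 these 3 lists held more calls in both directions: 4 higher and 4 lower, then 5 and 8, for the TCA cycle, 10 and 3, then 6 and 11, for the respiratory chain, and 3 and 3, then 3 and 2, for the pentose phosphate pathway.

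Genes of sterol synthesis were lower as well. Of 23 genes 14 fell, 0 rose and 9 did not pass (17 and 0 adjusted over the list alone), with a median log2 fold change of -0.85 (camera adjusted p = 5.37e-11, and adjusted p = 0.665 with an estimated correlation). The sterol carrier gene Stard4 fell from 194 ± 4.11 to 68.3 ± 2.05 CPM (-1.51, adjusted p = 0.00308). Lss, the lanosterol synthase gene, fell from 131 ± 2.34 to 46.4 ± 9.91 CPM (-1.5, adjusted p = 0.00867) and Mvd from 97.9 ± 1.44 to 38.7 ± 5.72 CPM (-1.34, adjusted p = 0.00733). The number of lower genes was 8 without WT 1 or without WT 2.

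**Figure D2:**
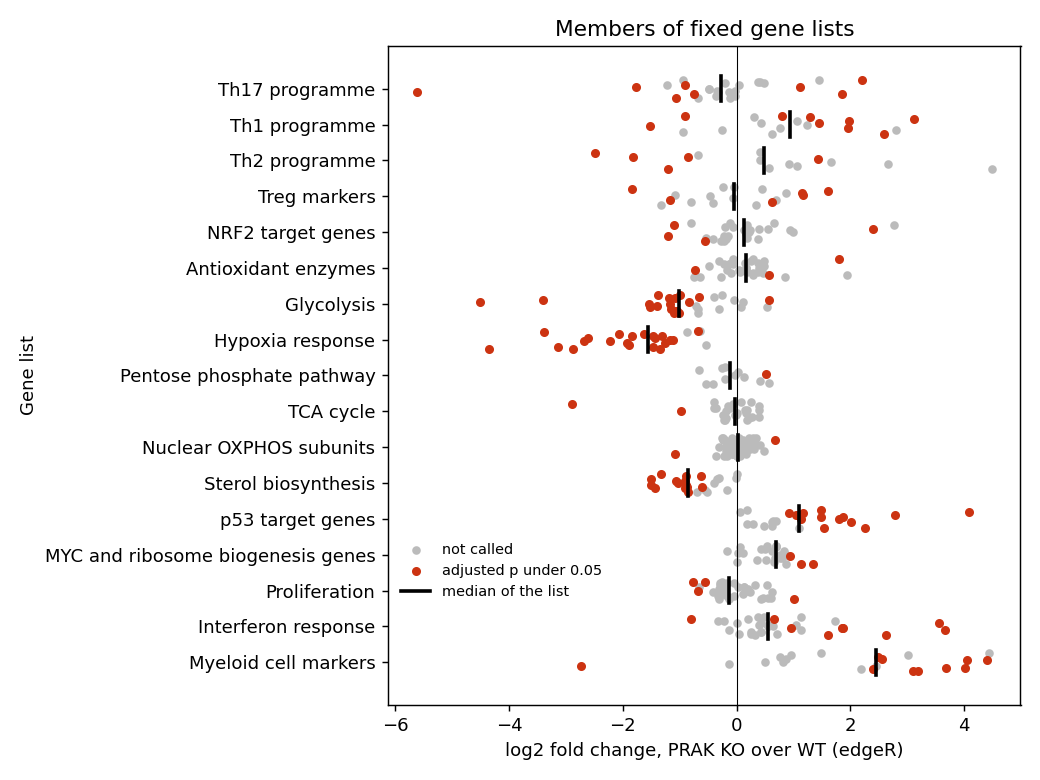
Log2 fold change of PRAK KO over WT for each tested member of 17 fixed gene lists, with red points for genes with an edgeR adjusted p under 0.05, grey points for the others and a black bar for the list's median. The medians of hypoxia response (-1.55), glycolysis (-1.01) and sterol biosynthesis (-0.85) lie below 0, and those of p53 target genes (1.11) and myeloid cell markers (2.46) lie above it.

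Targets of p53, the damage-response factor, were higher as a list. Of 23 genes 13 rose, 0 fell and 10 did not pass (14 and 0 adjusted over the list alone), with a median log2 fold change of 1.11 (camera adjusted p = 2.55e-13, and adjusted p = 0.665 with an estimated correlation). Zmat3 rose from 34.5 ± 2.12 to 165 ± 43.4 CPM (2.25 ± 0.21 SE, adjusted p = 0.00505). Aen, which encodes a nuclease of apoptosis, rose from 29.1 ± 1.87 to 84.5 ± 8.49 CPM (1.54 ± 0.13 SE, adjusted p = 0.00461), and the kinase gene Plk3 by 1.49 (adjusted p = 0.00602). The number of higher genes was 22 without KO 1, and without KO 2 it was 15, with 2 lower. Apoptosis regulators went both ways, with 8 of 25 higher and 3 lower (10 and 6 over the list alone) and a median of 0.16. The pro-apoptotic genes Bax (1.05, adjusted p = 0.00646) and Bbc3 (2.01, adjusted p = 0.00989) rose, as did Bcl2a1b, of an anti-apoptotic family with near-identical copies (1.2, adjusted p = 0.00960). That list was called higher (camera adjusted p = 0.0448) but not without WT 1 (0.110), without KO 2 (0.251), with upper quartile scaling (0.0511), with no filter on low counts (0.170) or with a stricter one (0.071), and its adjusted p was 0.902 with an estimated correlation. It held 5 higher and 0 lower genes without WT 1, 6 and 0 without WT 2, 12 and 6 without KO 1, and 9 and 7 without KO 2.

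Genes of growth and division gave few calls. Of 35 proliferation genes 1 rose and 3 fell (the same over the list alone, median -0.13, camera adjusted p = 0.872). Tyms rose (1.01, adjusted p = 0.0102), and Bub1 (-0.77, adjusted p = 0.0235), Ccnb2 (-0.68, adjusted p = 0.0333) and Cenpf (-0.56, adjusted p = 0.0350) fell. Without WT 2 none of these 4 was called (adjusted p = 0.0571, 0.103, 0.141 and 0.289). Without WT 1 the 3 that fell were not (0.117, 0.214 and 0.299). The KO mice differed here, with 3 higher and 19 lower genes without KO 1 (camera adjusted p = 0.0266, lower) and 12 higher and 6 lower without KO 2. Of 26 MYC and ribosome biogenesis genes 3 rose and 0 fell (9 and 0 over the list alone), with a median of 0.69 (camera adjusted p = 3.84e-05, and adjusted p = 0.902 with an estimated correlation). Srm, the spermidine synthase gene, rose from 83.6 ± 10.1 to 213 ± 48.4 CPM (1.35, adjusted p = 0.0146). The others were Rrp9 (0.94) and Nolc1 (1.12), whose calls were lost without WT 1 (adjusted p = 0.0508 and 0.0648) and without WT 2 (0.114 and 0.148). The number of higher genes in this list was 1 without either WT library, 14 without KO 1 and 21 without KO 2.

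Stress responses of the amino acid and unfolded protein pathways also separated the KO mice. Of 25 ATF4 target genes 4 rose and 2 fell (the same over the list alone, median 0.42, camera adjusted p = 0.312). Sesn2 (1.80) and Slc7a11 (2.39) rose, and Vldlr fell from 63.4 ± 6.51 to 3.35 ± 1.5 CPM (-4.24, adjusted p = 0.00319) with Stc2 (-2.88, adjusted p = 0.00902). Stc2 is also a member of the hypoxia response list, which fell. Without KO 2 this list was called higher (camera adjusted p = 4.93e-08) with 20 higher and 3 lower genes. Without KO 1 it held 5 higher and 8 lower, with a median of -0.215 (camera adjusted p = 0.226, lower). It held 2 and 2 without either WT library. Of 20 genes of the unfolded protein response 0 rose and 1 fell (0 over the list alone, median 0.16, camera adjusted p = 0.589), Xbp1 (-0.53, adjusted p = 0.0465, 0.369 without WT 1 and 0.357 without WT 2). Without KO 2 the camera adjusted p of that list was 0.0385, with 10 higher and 2 lower genes, and without KO 1 it held 2 and 5.

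In the p38 and atypical MAPK pathway, to which PRAK belongs, 1 of 18 genes rose and 2 fell (also over the list alone, median -0.10, camera adjusted p = 0.971). Mapkapk3, a kinase related to PRAK, rose from 192 ± 5.43 to 312 ± 39.5 CPM (log2 fold change 0.70, adjusted p = 0.0323), and the p38 activator gene Map2k6 fell from 14.8 ± 0.642 to 6.64 ± 1.93 CPM (-1.16, adjusted p = 0.0414) with Rps6ka4 (-0.48, adjusted p = 0.0473). None of the 3 was called without WT 1 (adjusted p = 0.217, 0.124 and 0.436) or without WT 2 (0.298, 0.183 and 0.363). Without KO 1 the list held 3 higher and 3 lower genes, and without KO 2 it held 5 and 5.

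Activation and interferon genes rose in part. Of 26 immediate early and T cell receptor response genes 10 rose and 2 fell (11 and 2 over the list alone), with a median log2 fold change of 0.61 (camera adjusted p = 0.000341, and adjusted p = 0.767 with an estimated correlation). Tnf rose from 66.9 ± 4.72 to 163 ± 19.98 CPM (1.28, adjusted p = 0.00738). Fosl1 rose from 4.32 ± 0.783 to 21.1 ± 3.69 CPM (2.28, adjusted p = 0.00681), and Ier3 fell from 126 ± 1.55 to 36.6 ± 3.65 CPM (-1.79, adjusted p = 0.00284). Of 33 interferon response genes 8 rose and 1 fell (10 and 1 over the list alone), with a median of 0.55 (camera adjusted p = 8.39e-05, 0.0662 without KO 2, and adjusted p = 0.839 with an estimated correlation). Bst2 rose from 22.2 ± 1.53 to 67.8 ± 12.3 CPM (1.61, adjusted p = 0.00683) and Iigp1 from 0.570 ± 0.0810 to 7.32 ± 0.900 CPM (3.67, adjusted p = 0.00470). Without either WT library 4 genes of each list rose, and without KO 1 the numbers were 17 and 28. Without KO 2 they were 13 and 10, with 4 and 3 lower. Myeloid markers, whose cells express many of these genes, rose in the same libraries (median 2.46).

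Markers of other cells were measured because an enrichment of naive CD4+ T cells can carry some over. Of 21 myeloid markers 9 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 fold change of 2.46 (camera adjusted p = 2.27e-07, and adjusted p = 0.665 with an estimated correlation). Mpeg1 rose from 0.960 ± 0.269 to 15.6 ± 3.66 CPM (4.01, adjusted p = 0.00415). Clec7a rose by 4.41 (adjusted p = 0.00415, and 5 without WT 2), and the neutrophil gene Ly6g fell from 8.06 ± 0.806 to 1.2 ± 0.290 CPM (-2.74, adjusted p = 0.00832). The number of higher markers was 5 without WT 1, 18 without KO 1 and 19 without KO 2. Their median was 3.19 without WT 2 (26 tested) and 1.76 without KO 2 (24 tested). Of 17 B cell markers 4 rose and 1 fell (5 and 1 over the list alone, median 0.89, camera adjusted p = 0.00748, and adjusted p = 0.906 with an estimated correlation). Ms4a1 rose from 0.545 ± 0.264 to 5.93 ± 0.860 CPM (3.43, adjusted p = 0.0102, and 4.02 without WT 2). By contrast, the MHC class II gene H2-Ab1 fell from 173 ± 24.2 to 67.5 ± 8.41 CPM (-1.36, adjusted p = 0.00884). Of 9 tested MHC class II genes it was the 1 called lower, and 1 was called higher, H2-Eb1 (1.62, adjusted p = 0.046). The median of these 9 genes was 0.765 (camera adjusted p = 0.443, a family test chosen after the results were seen). Cd74, also in the B cell list, rose (1.69, adjusted p = 0.0412). The B cell list was not called without KO 1 (0.486) or without KO 2 (0.230), and its higher genes numbered 5 without WT 1, 9 without WT 2, 1 without KO 1 and 2 without KO 2. Its median was 0.264 without WT 1 and 1.73 without WT 2.

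Markers of CD8 T and NK cells were not called as a list (1 of 12 rose, 4 over the list alone, median log2 fold change 0.59, camera adjusted p = 0.0564). The list was called without WT 2 (median 1.21, adjusted p = 2e-07) and with no filter on low counts (0.0411). It held 0 calls without WT 1, 4 higher without WT 2 or KO 2, and 2 higher and 1 lower without KO 1. Cd8a stood at 11.8 CPM in WT 1, 49.1 in WT 2, 185 in KO 1 and 104 in KO 2 (2.25, adjusted p = 0.0830, 1.55 without WT 1 with adjusted p = 0.0512, and 3.60 without WT 2 with adjusted p = 0.000969). Nkg7, a gene of cytotoxic granules, rose from 18.2 ± 6.40 to 70.8 ± 36.5 CPM (1.96, adjusted p = 0.0402), a call lost without WT 1 (0.197), WT 2 (0.110) or KO 2 (0.106, with a change of 1.31).

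Stromal and epithelial markers fell in 4 of 6 tested genes (also 4 over the list alone, median -1.46, camera adjusted p = 0.000651, 0.296 with no filter on low counts, and adjusted p = 0.665 with an estimated correlation). Those that fell include genes T cells express: Vim, the vimentin gene, from 3129 ± 123 to 1062 ± 279 CPM (log2 fold change -1.56, adjusted p = 0.0153), and Pecam1 from 90.9 ± 1.61 to 35.5 ± 1.74 CPM (-1.35, adjusted p = 0.00415). The lower genes of this list numbered 2 without WT 2.

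Of the other lists, edgeR called 0 of 8 erythroid and platelet markers (median log2 fold change 0.71, -0.346 without KO 2, camera adjusted p = 0.427), with 3 at an unadjusted p under 0.05, 1 called by DESeq2, 1 by limma on CPM and 2 by limma on FPKM. It called 0 of 8 gamma delta T and NKT markers (median 0.24, camera adjusted p = 0.589), with 3 at an unadjusted p under 0.05 and 2 called by each of the other tools. For 7 sex-linked genes (median -0.21, camera adjusted p = 0.761) and 8 replication-dependent histone genes (median 0.37, 1.09 without WT 1 and 1.35 without KO 1, camera adjusted p = 0.569) there were 0 calls by edgeR, DESeq2 or limma, with 2 and 1 at an unadjusted p under 0.05. Over the list alone 3 gamma delta T and NKT markers passed, and 0 in each of the other 3 lists. Without KO 1, edgeR called 8 histone genes higher and 1 lower of 14 tested, and 1 sex-linked gene lower. Without KO 2 it called 1 sex-linked gene higher and 3 lower. For the 12 NRF2 regulators the corresponding numbers were 0 by each tool and 2 at an unadjusted p under 0.05. Among 21 tested genes next to Mapkapk5 on chromosome 5, besides Mapkapk5 itself, Oas2 (2.63, adjusted p = 0.0391) and Oas1a (1.88, adjusted p = 0.0479) rose, both at under 4 CPM in every library and both also members of the interferon list (the same 3 calls over the list alone, median 0.16, camera adjusted p = 0.589). These calls were lost without WT 1 (adjusted p = 0.257 and 0.280) or WT 2 (0.387 and 0.203), and the list then held 0 calls, against 7 higher and 3 lower without KO 1 and 5 and 6 without KO 2.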

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

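All alternatives here were chosen before the data were examined. Of 118 named genes that changed, 0 reversed under any alternative. With library size as the only scaling 5 lost their call, with the limma fits 5 to 7, with DESeq2 1, with upper quartile scaling 3, with no filter 2, and with RLE scaling or without the robust option 0. Leaving out WT 1 lost 39 and leaving out WT 2 lost 44, where the spread rested on the KO pair, the wider one. Leaving out KO 1 or KO 2 lost 3 and 4. Other named genes gained a call: 9 with library size only, 3 with no filter, 7 to 11 with the limma fits, 18 with DESeq2, 5 without WT 2, 40 without KO 1 and 37 without KO 2. In each of these fits the lone library was assumed to vary like the other genotype. Leaving out a library gave 693 to 5999 changed genes, 209 to 2881 higher and 450 to 3118 lower. DESeq2 called 993 genes higher, and a 2-fold minimum left 1015 genes, 370 higher and 645 lower. The cause of the differences between tools was not tested. At 19418012 to 20125124 counts per library, 5241 genes fell under the filter on low counts and were not tested, and how far depth or the number of mice limited the calls was not compared.

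The mouse numbers recur in both genotypes, but nothing in the labels says that they pair the mice, and there are 2 pairs only. The differences between libraries 1 and 2 of WT and of KO had r = 0.175 across 12680 genes. With the number as a replicate block 2935 genes were called, 1338 higher and 1597 lower, of which 1684 were among the 1695. Of the named genes 3 lost their call and 22 gained one, the Treg list reversed (adjusted p = 0.834) and the CD8 T and NK list was called (adjusted p = 0.0314).

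Il17a reversed with library size only (0.0762) and ran from -0.91 to 0.52 with a library left out, and Gata3 from -0.49 to 1.63. Gclc reversed with library size only (0.0391) and in the limma fits (0.0183 on CPM, 0.024 on FPKM + 1 and 0.0244 on FPKM + 0.1) and ran from -0.33 to 0.16. Camera with an estimated correlation called 0 lists and fry 2, and glycolysis then had adjusted p = 0.230 with the estimated correlation. Lists that were never called reversed with no filter on low counts (Th2 0.957, naive T cell genes 0.947, pentose phosphate 0.947), with fry (pentose phosphate 0.964), and, for p38, with library size only (0.914), upper quartile scaling (0.981) and the stricter filter (0.916).

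With a library left out, adjusted p ran from 0.000113 to 0.279 for the Th17 list. For lists that turned direction it ran from 0.132 to 0.983 (Treg), 0.183 to 0.964 (naive), 0.885 to 0.996 (NRF2 targets), 0.163 to 0.900 (reactive oxygen), 0.486 to 0.991 (NRF2 regulators), 0.705 to 0.904 (pentose phosphate), 0.486 to 0.993 (respiratory chain), 4.93e-08 to 0.546 (ATF4), 0.0385 to 0.674 (unfolded protein), 0.0266 to 0.904 (proliferation) and 0.872 to 0.957 (p38).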

Other observations

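The tests of 16 gene families, the 3 tests of the myeloid marker pattern and the scan of genome windows were chosen after the results were seen. Chemokine ligands rose as a family: 10 of 19 tested genes rose and 1 fell (median log2 fold change 2.2, camera adjusted p = 2.1e-14, and adjusted p = 0.473 with an estimated correlation). Their share of all counts went from 0.0218% and 0.0197% in the WT libraries to 0.0685% and 0.0747% in the KO libraries. Ccl9 rose from 3.63 ± 1.07 to 35.2 ± 9.75 CPM (3.27, adjusted p = 0.00509), and the single fall was that of Ccl27a (-1.68, adjusted p = 0.0366). Of 18 interleukin genes 5 rose and 1 fell (camera adjusted p = 0.0490, and adjusted p = 0.479 with an estimated correlation). Myeloid markers, whose cells express many chemokine, interleukin 1 and C-type lectin genes, rose in the same libraries (median 2.46). Il2 rose from 15.8 ± 4.73 to 191 ± 121 CPM (3.59, adjusted p = 0.0146) and Il1a from 1.97 ± 0.173 to 30.7 ± 16.9 CPM (3.96, adjusted p = 0.00892).

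Both metallothionein genes fell, Mt1 from 564 ± 119 to 28.0 ± 28.0 CPM (log2 fold change -4.33, adjusted p = 0.0280) and Mt2 from 361 ± 89.0 to 13.4 ± 13.6 CPM (-4.75, adjusted p = 0.0224, 0.56 without WT 1 and 0.658 without WT 2), with a family adjusted p of 0.0214 (adjusted p = 0.567 with an estimated correlation). Of 7 collagen-modifying enzymes, which were hydroxylases and the lysyl oxidases Loxl2 and Loxl3, 3 fell. They were Plod2 (-1.38, adjusted p = 0.00500), P4ha1 (-1.17, adjusted p = 0.00895) and P4ha2 (-3.15, adjusted p = 0.00209), with a family adjusted p of 0.00185 (adjusted p = 0.479 with an estimated correlation). P4ha1 and P4ha2 are also in the hypoxia response list, so this family result is not separate from the fall of that list. Of 24 C-type lectin genes 5 rose, among them Clec4n (4.78, adjusted p = 0.00884; 4.04 without KO 2) and the myeloid marker Clec7a (4.41, adjusted p = 0.00415), with a family adjusted p of 0.0231 (adjusted p = 0.479 with an estimated correlation). Of the 16 families 5 passed with the preset correlation. Cytosolic ribosomal protein genes (2 of 79 called, median -0.07, adjusted p = 0.877) and MHC class I genes (4 of 16 called, median -0.02, adjusted p = 0.118) did not. The median of the latter hides large single changes. H2-Q10 (-4.54, adjusted p = 0.00179), H2-Q2 (-3.43, adjusted p = 0.00602) and H2-Q1 (-2.37, adjusted p = 0.0194) fell, and H2-Q6 (1.54, adjusted p = 0.0121) rose. These H2-Q genes share reads with near-identical copies.

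The lower level of glycolysis and hypoxia response genes in KO cells was set against 2 technical explanations. After a correction of all fold changes for GC content and gene length, the median over the 52 genes was -1.19 (95% bootstrap interval -1.44 to -1.05) against -1.17 before, which argues against such a bias. Dilution of T cell RNA by cells other than T cells would have lowered T cell genes as far, but the median of 17 such genes was -0.158. Its bootstrap interval, over genes and not mice, was -0.207 to 0.363, and the genes ran from -0.46 (Cd2) to 0.94 (Cd5). CD8 T cells share most of these genes, so the median does not bear on dilution by them. Cd4, which they lack, changed by -0.13 (SE 0.30) and stood at 516 and 939.5 CPM in KO, against 185 and 104 for Cd8a. Dilution by CD8 T cells would have lowered Cd4 at least as far as the 52 genes. The values argue against it as the main source of their fall, as far as 1 gene can. A smaller contribution of CD8 T cells stays open. The genotype stays open as an explanation. So do differences in culture density or oxygen between the mice, which went with the genotype if they existed and were not measured.

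Of 21 tested myeloid markers 17 (81%) lay higher in both KO libraries than in both WT libraries. Carry-over of myeloid cells is a candidate explanation, but that number is the pattern itself and so decides nothing, and the explanation cannot be told apart from the others that stay open. The markers with the highest KO mean were Ctss (41.0 and 46.0 CPM in WT, 56.1 and 98.0 in KO), Lyz2 (1.54 and 3.08 in WT, 12.7 in KO 1 and 64.3 in KO 2) and Cd68 (10.4 and 16.6 in WT, 21.2 and 54.5 in KO). In addition, 12 of the 21 had a mean of at least 1 CPM in WT cells, and 1 is in another list. The enrichment of naive CD4+ T cells stated in the labels would lower the share of such cells but need not remove them. A library size difference is argued against by a KO to WT ratio of 0.987. A lower share of T cells with all other blood cell types up alike cannot be told apart from myeloid carry-over. The intervals of the medians of 0 of the 3 other lists (B cells 0.588 to 1.62, CD8 T and NK cells 0.208 to 2.06, erythroid cells and platelets -0.0766 to 1.63) lay apart from that of the myeloid markers (0.954 to 3.11). That explanation also predicts a fall of T cell genes, which was not shown (median of 17 genes -0.158, interval -0.207 to 0.363). A small fall would not stand out among genes that ran from -0.46 to 0.94, so this does not count against it. Stromal and epithelial markers, some of which T cells express, had a median of -1.46 and were not part of this check. Expression of the myeloid markers by the KO T cells stays open too.

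A knockout made in cells of another strain can keep that strain's variants around the targeted gene, which could give large differences there. Within 10 Mb of Mapkapk5, 2 of 182 tested genes had a called change of at least 4-fold, against 440 of 12439 elsewhere, an odds ratio of 0.303 (95% interval 0.0363 to 1.12, two-sided Fisher exact p = 0.0989), which argues against that region as the source of the extreme changes. In a scan of 520 windows of 5 Mb, 2 held more such genes than the rest of the genome: chromosome 5 from 90 to 95 Mb (8 of 25 genes, adjusted p = 0.000878) and chromosome 7 from 35 to 40 Mb (7 of 22, adjusted p = 0.00208). The binomial test of the scan took genes as independent, which neighbouring genes of 1 family, such as Cxcl3, Cxcl9 and Cxcl10, need not be. In the first, Cxcl3, Cxcl9, Cxcl10, Mthfd2l, Areg and Afp rose, and Ccng2 (177 CPM in WT, 41.5 in KO, log2 fold change -2.09) and Stbd1 fell. Of these, Cxcl9, Areg, Afp and Stbd1 were at under 3 CPM in every library. In the second, Plekhf1 (39.6 and 4.71 CPM, -3.07), Tshz3 (5.33 and 0.491, -3.42), Gm5591, Rgs9bp and Gm6818 fell, and Zfp939 (3.13) and Cebpa (2.63) rose. All of these but Plekhf1 and Tshz3 were at under 3 CPM in every library.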
